A study of Mus musculus with 9 samples.

How the data were processed

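The series measured transcript levels in a CD45-depleted fraction of the mouse thymus, the organ in which T cells mature. Per the labels' protocols, hematopoietic cells were removed with magnetic beads against CD45, a surface protein of white blood cells, and material of several mice was pooled for each sample. The protocol names the pooled cells with an abbreviation, ECs, that it does not explain, so the labels leave open whether the samples held all stromal cells or a subset. Samples of female C57BL/6J mice formed 3 groups: untreated, day 4 after irradiation and day 7 after irradiation, with 3 samples in each. The labels call the treatment SL-TBI. Sublethal total body irradiation is the usual reading of that abbreviation in this field. Each sample was hybridised to 1 Affymetrix Mouse Genome 430 2.0 array, a 1-colour array on which each probe set reads sequence near the 3-prime end of a transcript. The labels do not say whether the 3 samples of a group came from separate pools of mice. The p-values therefore measure the spread between these pooled samples, which may be technical.

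The deposited table held 1 log2 value per probe set and array. The values were made with GCRMA, per the submitters' processing notes, a method that corrects the background by probe sequence, normalizes the arrays and summarises the probes of a probe set; its version and settings are not given in the sources used here. The log base was inferred from the values, since the labels do not state it. Between 26.1% and 27.2% of the values of each array lay at the lowest value of 2.27, so differences at that floor are compressed. No scanner files were used here, and the deposited normalization was kept.

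The table held 45101 probe sets, of which 64 were control probe sets. A single gene symbol was given for 34945, several for 932 and none for 9160, and 34754 were matched to the RefSeq gene table by their gene identifier, which changed 0 symbols. Probe sets with several symbols or none entered no gene comparison. For each of the 18193 genes, the probe set with the highest mean over all 9 arrays was kept. Genes with a log2 value of at least 4 on at least 3 of the 9 arrays were tested. This left 10937 genes, of which 6907 had more than 1 probe set, and set aside 7256 dim genes. A gene below 4 on every array of a group was treated as below the detection level there, and its fold change is given as a lower bound computed from that level.

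All 9 arrays entered 1 linear model with the group as its only term, fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, so that the 3 comparisons shared an estimate of the spread. P-values were adjusted with the Benjamini-Hochberg method at 0.05, and an F-test covered all 3 groups. The 3 comparisons were day 4 against untreated, day 7 against untreated and day 7 against day 4. Every adjusted p of a gene below comes from that limma model. Values per group are means of log2 values with their standard deviation over 3 arrays, differences are on the log2 scale with their standard error (SE), and the number of arrays limits the precision. The control probe sets of Actb and Gapdh were compared by their 3-prime minus 5-prime value with two-sided exact permutation tests, in which 3 arrays against 3 cannot give a p below 0.1. Figures were drawn with matplotlib 3.10.9 in Python 3.11.

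The comparisons, the model, the filter, the alternatives other than those named as added below, the rule for named genes and 45 gene lists were fixed before the data were examined. The lists covered hematopoietic and stromal cell types of the thymus, thymic epithelial subsets, signalling pathways and stress programmes. Of their 580 genes, 536 had a probe set with a single symbol and 431 were tested. The 38 lists with at least 3 tested members were compared with all other genes by limma's camera at a preset correlation of 0.01 between genes, and 7 lists were not tested. At the preset value 14, 22 and 17 lists were shifted in the 3 comparisons in the order above, and 0 in each with a correlation estimated for every list, so no list call holds under that stricter setting, which gave 4, 3 and 5 lists at an unadjusted p under 0.05, while fry gave 29, 29 and 20 at an adjusted p under 0.05. The counts of list members are given over all genes tested and, where it differs, adjusted over the list alone.

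Named genes followed a rule of 3 parts. The rule took 18 genes fixed beforehand (Bmp4, Foxn1, Dll4, Fgf7, Fgf21, Il7, Kitl, Ccl25, Cxcl12, Il22ra1, Ptprc, Cd3e, Epcam, Pecam1, Pdgfra, Cdkn1a, Mdm2 and Mki67), the 6 largest rises and 6 largest falls of each comparison past the threshold whose groups did not overlap, and up to 3 members of each list with the smallest adjusted p. For a list without members past the threshold it took up to 2 members with the largest difference, as values. The alternatives were no filter on dim genes, a level of 6, the mean of all probe sets of a gene, every probe set on its own, an intensity trend in the variance prior, array weights, centring on the mean of the kept genes, quantile normalization, a replicate block, an adjusted p of 0.01, a difference of at least 2-fold, leaving out each array in turn, fitting only the 6 arrays compared, and camera with an estimated correlation or limma's fry for the lists. Centring each array on the mean of the epithelial list or on the mean of 4 stromal lists (epithelial cells, endothelial cells, fibroblasts and pericytes) was added after seeing the data.

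The steps were tested on simulated data made from the values of the untreated and day 4 arrays for 10937 genes. Of 50 genes changed by each size, 54%, 72%, 98% and 98% were recovered at log2 differences of 0.5, 1, 2 and 3. Of 10737 unchanged genes 6 were called, and of 20 unchanged lists 0 were called. The simulated genes were drawn independently and the simulated lists were made of random genes. In the real data the estimated correlation exceeded the preset value in 36 of 38 lists. The 0 therefore does not show how often lists of correlated genes are called in error.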

Results

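Transcript levels were measured in CD45-depleted cells of the mouse thymus, a preparation aimed at the stroma that supports developing T cells. The depletion left hematopoietic transcripts in the untreated samples, in which Ptprc, the gene of CD45, read 12.22 ± 0.25 and the mean of the thymocyte list was 9.17 ± 0.23 (log2, SD, n = 3). Their list means were 11.14 ± 0.08 for cortical epithelium, 10.12 ± 0.29 for fibroblasts and 4.78 ± 0.91 for endothelium. The untreated samples were thus a mixture and not pure endothelial or epithelial cells. The 9 arrays formed 3 groups of 3: untreated mice, mice at day 4 and mice at day 7 after irradiation. The labels give a dose of 550 cGy. Between 42.1% and 44.2% of all probe sets lay at or above the detection level on each array. Across all probe sets, which are not independent replicates, correlations between arrays of 1 group were 0.987 to 0.993 in untreated, 0.995 to 0.996 at day 4 and 0.996 at day 7. Untreated arrays correlated with day 4 arrays at 0.943 to 0.964 and with day 7 arrays at 0.959 to 0.975, and day 4 with day 7 arrays at 0.984 to 0.987. The number of arrays limits the precision of every difference.

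The comparison of day 4 with untreated asked how the stromal preparation differed early after damage. Transcripts of thymocytes and of dividing cells were far lower at day 4. In a CD45-depleted fraction, thymocyte transcripts come from cells that the depletion left. How completely each sample was depleted was not measured here. Differences in these transcripts at day 4 or day 7 therefore do not measure thymocyte numbers in the thymus. Ptprc, which encodes CD45, the protein used for depletion, read 12.22 ± 0.25 in untreated (log2, mean ± SD, n = 3) and 4.64 ± 0.53 at day 4, a 191-fold fall (difference -7.58, SE 0.25, adjusted p 6.9e-08). Rag1, an enzyme of T-cell receptor gene rearrangement, fell by at least 557-fold, the chemokine receptor gene Ccr9 by at least 213-fold, and the co-receptor genes Cd8b1 and Cd8a by at least 123-fold and 74.7-fold, while Trbv1 differed by -7.46. The mean of all probe sets gave -4.76 for Ccr9 and -3.80 for Trbv1. All 18 tested members of the thymocyte and T-cell list fell, with a median difference of -5.73, or -5.48 with genes below the detection level at their bounds. Cd3e, a subunit of the T-cell receptor complex, fell from 9.52 ± 0.26 to 5.57, the same value on all 3 day 4 arrays (difference -3.95, SE 0.12, adjusted p 4.8e-08). A tied value has no spread, so this SE and adjusted p may be too small. Whether 5.57 was a measured level was not tested, and the fall may be a lower bound. Mki67, a marker of dividing cells, went from 11.16 ± 0.62 to 4.95 ± 0.04, a 73.7-fold fall (difference -6.20, SE 0.26, adjusted p 2.7e-07). All 17 mitosis genes fell (median -4.95, with bounds -4.32), among them Ube2c at -5.95 and Birc5 at -5.40, and all 16 DNA replication genes fell (median -2.39, with bounds -2.12), among them the helicase genes Mcm5 at -3.58 and Mcm2 at -3.10. By camera, the adjusted p was 1.1e-18 for thymocytes, 1.0e-16 for mitosis and 1.2e-12 for DNA replication. With an estimated correlation, the adjusted p values were 0.246, 0.406 and 0.406.

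Other blood cell genes were lower as well. All 3 erythroid genes fell (median -3.38, camera adjusted p 0.00535, and adjusted p 0.421 with an estimated correlation), including Alas2, the first enzyme of heme synthesis in red cells, by at least 41.6-fold (27.6-fold without untreated replicate 3) and the transferrin receptor gene Tfrc at -3.38. The erythroid median was -1.90 with the mean of all probe sets, which gave -1.21 for Tfrc, and lay near 0 without the filter on dim genes. Of 6 neutrophil genes 5 fell, with S100a8 at -2.77 and S100a9 at -2.45. Their median was -2.26, -1.68 with bounds and -1.09 without the filter on dim genes (camera adjusted p 0.0120, and adjusted p 0.710 with an estimated correlation). Of 12 DNA repair genes 7 fell and 2 rose, with Msh6 at -1.98 and Parp1 at -1.39 (median -0.80, camera adjusted p 0.0150, and adjusted p 0.406 with an estimated correlation). The DNA repair call was lost with the mean of all probe sets (median -0.13, adjusted p 0.123), and its median was -1.23 without the filter. Of 6 macrophage genes 3 fell and 1 rose, and the list was not shifted (median -0.58, adjusted p 0.365).

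Fibroblast and matrix genes were higher at day 4. All 14 fibroblast genes rose (median 1.27), and Pdgfra, a growth factor receptor of mesenchymal cells, read 9.35 ± 0.42 in untreated and 10.61 ± 0.27 at day 4 (difference 1.26, SE 0.21, adjusted p 8.7e-04). Lum, a small matrix proteoglycan gene, differed by 1.77 and Loxl1, a collagen and elastin cross-linking enzyme gene, by 2.17. Of 21 extracellular matrix genes 19 rose and 2 fell (median 1.04), with Col18a1 at 1.80 and Nid2 at 1.40. All 7 complement genes rose (median 1.80), among them C1ra at 2.26, C2 at 2.31 and Cfb at 2.47. Of 12 WNT genes 11 rose and 1 fell (median 1.5), with Sfrp2 at 3.21 and Rspo3 at least 2.92-fold higher, and of 13 Notch genes 11 rose (median 1.17), with the target genes Hey1 at 2.07 and Hes1 at 1.19. Camera gave adjusted p values for fibroblasts, matrix, complement, WNT and Notch of 0.00473, 0.00594, 0.0111, 0.0111 and 0.00535. With an estimated correlation, their adjusted p values were 0.710, 0.710, 0.710, 0.406 and 0.421.

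Several growth factors of the thymic stroma were higher at day 4. Bmp4, a secreted morphogen, rose 2.69-fold from 6.31 ± 0.57 to 7.74 ± 0.21 (difference 1.43, SE 0.25, adjusted p 1.0e-03). Fgf7, a mesenchymal growth factor for epithelium, rose 7.56-fold from 5.32 ± 0.86 to 8.24 ± 0.26 (difference 2.92, SE 0.36, adjusted p 1.3e-04), and the mean of its probe sets gave 1.92. Foxn1, the master regulator of thymic epithelium, rose from 8.60 ± 0.08 to 9.63 ± 0.17 (difference 1.03, adjusted p 1.5e-04). The Notch ligand gene Dll4 rose from 4.49 ± 0.10 to 5.58 ± 0.10 (difference 1.09, adjusted p 1.1e-04). Il7, a survival factor for early T cells, rose from 10.30 ± 0.07 to 11.73 ± 0.10 (difference 1.43, SE 0.09, adjusted p 3.0e-06). Kitl rose by 0.55 (adjusted p 0.0095) and the chemokine gene Cxcl12 by 0.51 (adjusted p 0.0075), but both calls were lost after centring on the epithelial list (0.25 and 0.22) and both directions turned after centring on the 4 stromal lists. Fgf21, an endocrine factor, fell from 8.25 ± 0.88 to 6.09 ± 0.30 (difference -2.16, SE 0.38, adjusted p 0.0011). The chemokine gene Ccl25 read 14.35 ± 0.14 and 14.22 ± 0.06 (adjusted p 0.240), and Il22ra1 stayed below the detection level in all groups.

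The epithelial genes moved apart. Epcam, a surface marker of epithelium, read 11.18 ± 0.45 in untreated and 11.08 ± 0.13 at day 4 (adjusted p 0.657), but was called lower without untreated replicate 3 (-0.35, adjusted p 0.033). Of 13 general epithelial genes 7 rose and 1 fell (median 0.33, adjusted p 0.547), with Krt5 at 1.74. Of 14 cortical genes 9 rose and 1 fell (median 0.39, adjusted p 0.142), with the transcription factor gene Pax1 at 1.20. In contrast, 7 of 8 genes of keratinising epithelium fell (median -1.45), with Flg at -2.31 and Krt10 at -1.40 (camera adjusted p 0.0111, and adjusted p 0.710 with an estimated correlation). Of 8 medullary genes 3 fell, including Aire at -1.32, the regulator of tissue-restricted antigens, and of 10 such antigens 2 fell, Csn2 at -1.82 and Crp by at least 3.21-fold. Neither list was shifted (medians -0.58 and -0.41, adjusted p 0.0879 and 0.0734). The endothelial list had 6 genes that rose, 0 that fell and 11 past neither side (median 0.95, adjusted p 0.339). Pecam1, an endothelial adhesion molecule gene, read 4.04 ± 1.18 in untreated and 2.92 ± 0.21 at day 4, below the detection level, so that no size of the difference is given (adjusted p 0.081). The adjusted p was 0.0039 without untreated replicate 2, 0.011 with array weights and 0.038 after centring on the epithelial list. Untreated replicate 3 stood apart in these lists. Its endothelial mean was 5.83 against 4.18 and 4.34 in the other untreated arrays, its keratinising mean 6.87 against 8.13 and 8.24, its medullary mean 6.97 against 8.01 and 8.13, and its antigen mean 6.31 against 7.44 and 7.69. Without it the medians were 1.53 for endothelium (adjusted p 0.0028), -0.97 for medulla (0.0025), -0.89 for the antigens (0.0028) and 0.48 for cortex (0.047), so that these 4 lists were called. Medulla and antigens were also called after centring on the epithelial list (-0.87 and -0.71, adjusted p 0.023 and 0.028), and cortex without the filter (0.39, 0.021). Without day 4 replicate 1 the antigen list was also called (-0.58, adjusted p 0.040).

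Of the stress programmes, the immediate early list was shifted at day 4 and the p53 target list was not. Cdkn1a, a cell cycle inhibitor induced by p53, rose 3.82-fold from 8.87 ± 0.40 to 10.80 ± 0.12 (difference 1.93, SE 0.19, adjusted p 3.9e-05). The p53 target gene Mdm2 read 7.27 ± 0.13 and 6.97 ± 0.17 (-0.31, adjusted p 0.061), and was called lower without untreated replicate 2 (-0.37, adjusted p 0.045), without day 4 replicate 2 (-0.40, adjusted p 0.029) and after centring on the epithelial list (-0.61, adjusted p 0.036). It was also called lower with array weights (-0.42, adjusted p 0.0075), after centring on the kept genes (-0.41, 0.017) and after quantile normalization (-0.35, 0.031). Of 20 p53 targets 12 rose and 5 fell, 6 adjusted over the list alone, with Ddit4l at 2.84 and Ccng1 at 1.28 (median 0.81, adjusted p 0.225). Of 14 immediate early genes, induced by stress and dissociation, 10 fell, 11 adjusted over the list alone, with Nr4a1 at -4.70 and Dusp1 at -1.75 (median -1.47, camera adjusted p 6.3e-04, and adjusted p 0.710 with an estimated correlation). Day 4 replicate 1 had a mean of 8.51 in this list against 9.67 and 9.73, and without it the median was -0.91. Of 10 cholesterol synthesis genes 5 fell and 2 rose, with Idi1 at -2.47 and Cyp51 at -1.48 (median -0.41, camera adjusted p 0.0310, and adjusted p 0.710 with an estimated correlation). The cholesterol call was lost without untreated replicate 3 (-0.37, adjusted p 0.067), without day 4 replicate 2 (-0.40, 0.059), with the mean of all probe sets (-0.18, 0.068) and after centring on the epithelial list (-0.71, 0.066). Largest among the other rises were Cox8b, a cytochrome oxidase subunit of brown fat and muscle, at least 17.5-fold, Cyp2e1 at least 9.07-fold (5.91-fold without day 4 replicate 1), Mmp11 at 4.03, Car3 at 3.85 (2.48 with the mean of all probe sets), Sned1 at 3.78 and Cpxm1 at 3.76.

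At day 4, 6916 of 10937 genes differed from untreated, 4574 higher and 2342 lower, and 1583 and 957 of these by at least 2-fold. The groups did not overlap for 7401 genes (67.7%, against 10% by chance). Nor did they for 133 of the 136 named genes past the threshold, a count raised by the naming rule, which favours such genes. Of the changed genes 66.1% were higher, and the median of all genes stood at 0.196. Centring on the mean of the kept genes gave 3906 higher and 2847 lower, on the epithelial list 2119 and 2731 (43.7% higher) and on the 4 stromal lists 1078 and 4977 (17.8%), which moved the median of all genes by -0.107, -0.298 and -0.658. The 3-prime minus 5-prime value of the control probe sets, a measure of RNA quality, was higher at day 4, 3.13 ± 0.17 against 2.28 ± 0.15 for Actb and 1.37 ± 0.24 against 0.90 ± 0.13 for Gapdh (exact permutation p 0.1 each, the smallest possible with 3 against 3).

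**Figure D1:**
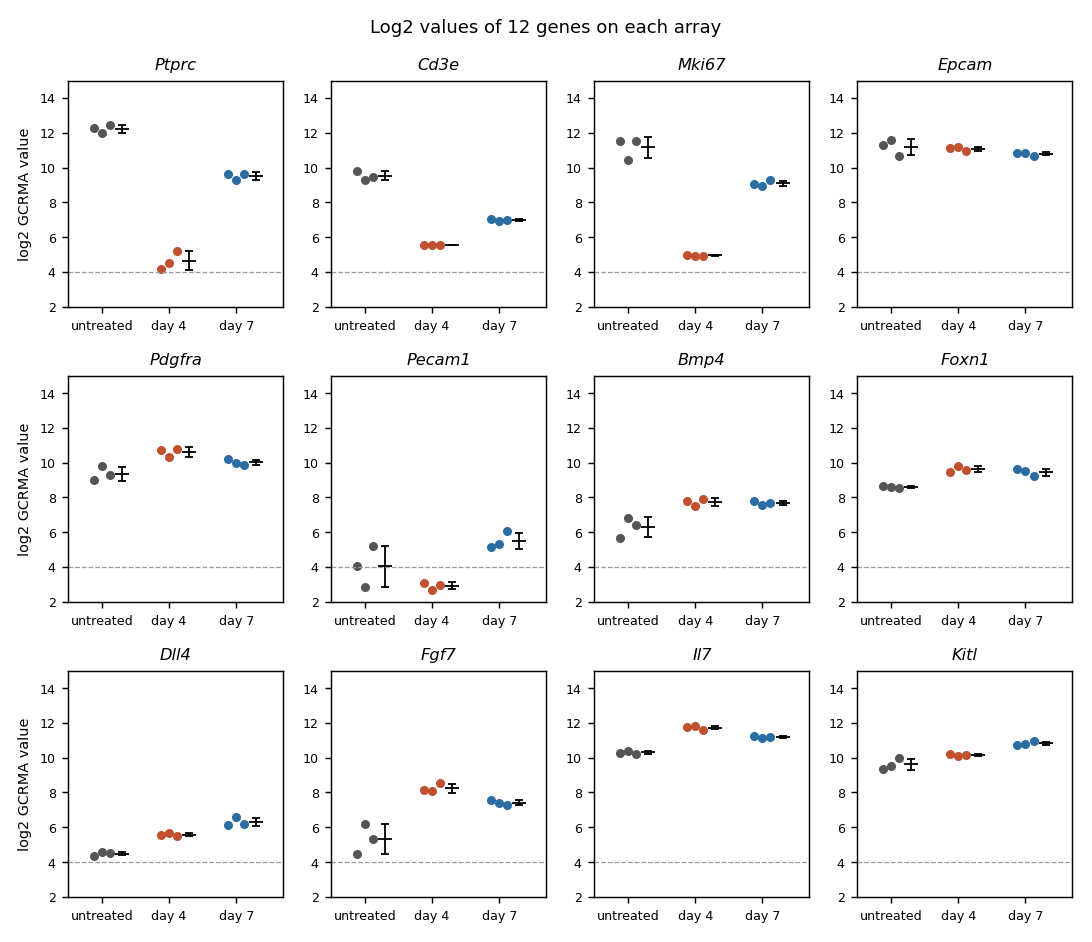
Log2 values of 12 named genes on each array (dots) in untreated, day 4 and day 7 samples, with the mean and SD (bars, n = 3) and the detection level of 4 (dashed line). Ptprc, Cd3e and Mki67 were lowest at day 4 and higher again at day 7, below untreated, whereas the Bmp4 means were 6.31, 7.74 and 7.69 and the Il7 means 10.30, 11.73 and 11.18, and Il7 at day 7 and Kitl at day 4 turned below untreated after centring on the 4 stromal lists. That centring moved every gene by -0.658 at day 4 and -1.19 at day 7, so any smaller rise turns.

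The comparison of day 7 with untreated asked what still differed later. The endothelial list was higher as a whole at day 7. All 17 of its genes rose, with a median of 2.71 (camera adjusted p 2.6e-05, and adjusted p 0.379 with an estimated correlation). Kdr, a receptor for vascular endothelial growth factor, rose 8.30-fold from 4.35 to 7.41 (difference 3.05, adjusted p 2.4e-04, n = 3 per group). The lipase anchor gene Gpihbp1 rose from 4.55 to 8.72, Emcn differed by 3.58, Adgrl4 by 3.52, and Podxl by 3.41 (1.74 with the mean of all probe sets). The array means of the list were 7.40, 7.29 and 7.32 at day 7, against 4.18, 4.34 and 5.83 in untreated. Pecam1 read 4.04 ± 1.18 in untreated and 5.51 ± 0.47 at day 7 (difference 1.47, SE 0.50, adjusted p 0.034). The Pecam1 call was lost without untreated replicate 1 (1.48, adjusted p 0.078) or 2 (0.87, 0.072), without day 7 replicate 1 (1.64, 0.051), 2 (1.57, 0.062) or 3 (1.20, 0.115), and without the filter on dim genes (0.113). Of 12 angiogenesis genes 9 rose and 1 fell (median 1.07, camera adjusted p 0.0325, and adjusted p 0.372 with an estimated correlation), with Apln at 1.53 and Vegfc at 1.26. That call was lost with the mean of all probe sets (0.94, adjusted p 0.055), and the median turned to -0.12 after centring on the 4 stromal lists.

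**Figure D2:**
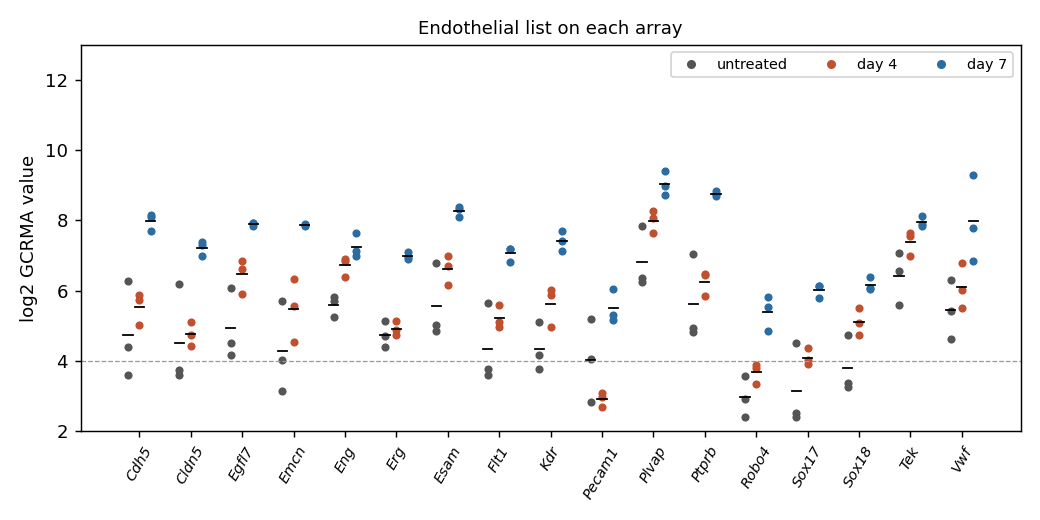
Log2 values of the 17 tested genes of the endothelial list on every array (dots), with group means (ticks) and the detection level of 4 (dashed line). The list mean was 4.78 ± 0.91 in untreated, where replicate 3 read 5.83, 5.58 ± 0.37 at day 4 and 7.34 ± 0.06 at day 7 (SD, n = 3).

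Genes of tissue-restricted antigens, of the medulla and of keratinising epithelium were lower at day 7. Of 10 antigen genes 9 fell, 10 adjusted over the list alone, with a median of -2.68, or -2.40 with bounds. Csn2, a milk casein gene, fell 7.92-fold, and the apolipoprotein gene Apoa4 fell 8.06-fold. Of 8 medullary genes 7 fell (median -1.51, with bounds -1.29). Aire fell 3.92-fold (difference -1.97, adjusted p 8.0e-04), Spib differed by -1.84 and Tnfrsf11a by -1.93 (-1.05 with the mean of all probe sets). All 8 keratinising genes fell (median -1.92, with bounds -1.76), with Calm4 at -3.43 and Flg by at least 6.14-fold. The camera adjusted p values were 1.2e-04, 0.00446 and 2.4e-04, and with an estimated correlation the adjusted p values were 0.372, 0.420 and 0.372. The array means of these lists in untreated replicate 3, 6.31, 6.97 and 6.87, lay below the other untreated arrays and above all day 7 arrays, and without it the medians were -3.14, -1.95 and -2.43. Of 14 cortical genes 10 rose (median 0.52, camera adjusted p 0.00359, and adjusted p 0.372 with an estimated correlation), with Slc46a2 at 1.24, but the cortical median turned to -0.67 after centring on the 4 stromal lists. Epcam read 10.79 ± 0.08 (difference -0.40, adjusted p 0.115; -0.65 and adjusted p 0.0029 without untreated replicate 3), and of 13 general epithelial genes 6 rose and 4 fell (median 0.07, mean -0.08, adjusted p 0.818).

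Mesenchymal and signalling lists were above untreated at day 7. Of 14 fibroblast genes 10 rose (median 0.69), with Lum at 1.24 and Loxl1 at 1.69. Of 21 matrix genes 18 rose (median 0.93), with Col18a1 at 1.41 and Nid2 at 1.32. Of 11 pericyte and smooth muscle genes 6 rose (median 0.85, with bounds 0.83; 0.47 and adjusted p 0.021 without day 7 replicate 3), with the channel gene Kcnj8 at 2.90 and its partner Abcc9 at 1.95. Of 6 mesothelial genes 5 rose (median 1.93), with Wt1 at 2.01 and Muc16 at 1.83. Of 12 WNT genes 10 rose and 1 fell (median 1.35, with bounds 1.12), with Sfrp2 at 2.25. Of 13 Notch genes 10 rose (median 0.80, 0.46 with the mean of all probe sets), with Hey1 at 1.46. Of 19 BMP genes 13 rose (median 0.61), with the inhibitory Smad6 at 1.74. Of 11 FGF genes 9 rose, 10 adjusted over the list alone, and 1 fell (median 1.01, 0.61 with the mean of all probe sets), with Etv5 at 1.20. Of 7 complement genes 6 rose (median 0.84), with C2 at 1.77, and this call was lost with the mean of all probe sets (adjusted p 0.054). For these 9 lists, in this order, the camera adjusted p values were 0.00601, 1.2e-04, 0.0144, 0.00805, 0.00359, 0.00679, 0.00665, 0.00611 and 0.0250. With an estimated correlation, the adjusted p values were 0.494, 0.379, 0.372, 0.372, 0.372, 0.372, 0.379, 0.379 and 0.420. Centring on the 4 stromal lists, which include fibroblasts, pericytes and the endothelial list, took 1.19 off every gene, so that any smaller rise turns. Under it the medians of fibroblasts, matrix, pericytes, Notch, BMP, FGF and complement turned to -0.50, -0.26, -0.34, -0.39, -0.58, -0.18 and -0.35, while mesothelium and WNT kept their direction at 0.74 and 0.16.

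Bmp4 was 2.59-fold above untreated at day 7 (7.69 ± 0.11, n = 3, difference 1.37, SE 0.25, adjusted p 1.8e-03), Fgf7 4.24-fold (7.41 ± 0.14, difference 2.08, adjusted p 0.0013) and Dll4 3.53-fold (6.31 ± 0.24, difference 1.82, adjusted p 2.2e-05). Kitl, encoding stem cell factor, rose by 1.21 (adjusted p 2.3e-04). Foxn1 rose by 0.85 (adjusted p 7.2e-04), Il7 by 0.88 (adjusted p 1.0e-04) and Cxcl12 by 0.56 (adjusted p 0.0062), and these 3 turned after centring on the 4 stromal lists, while centring on the epithelial list ended the Cxcl12 call (0.64, adjusted p 0.056). Pdgfra rose by 0.66 (adjusted p 0.029), a call that was lost without untreated replicate 1 (0.47, adjusted p 0.101) or 3 (0.61, 0.072) and without day 7 replicate 1 (0.57, 0.092) or 2 (0.68, 0.062), and that turned after centring on the 4 stromal lists. Ccl25 rose by 0.24 (adjusted p 0.049). The Ccl25 call was lost on leaving out any array but untreated replicate 3 (0.17 to 0.25, adjusted p 0.061 to 0.122), with the mean of all probe sets (0.12) and after centring on the kept genes (0.21) or the epithelial list (0.32), and it turned after centring on the 4 stromal lists. Fgf21 fell by 2.30 (adjusted p 0.0011). Of 9 homing and survival factors of T-cell progenitors 7 rose (median 0.69, camera adjusted p 0.00805, and adjusted p 0.372 with an estimated correlation; -0.50 after centring on the 4 stromal lists). Of 10 thymic regeneration factors 8 rose and 2 fell (median 0.90, camera adjusted p 0.0294, and adjusted p 0.372 with an estimated correlation). The regeneration call was lost without the filter (0.66, adjusted p 0.070) and after centring on the epithelial list (0.97, 0.067), and the median turned to -0.29 after centring on the 4 stromal lists.

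Blood cell and division genes remained below untreated at day 7. Ptprc read 9.51 ± 0.22, 6.55-fold lower (difference -2.71, adjusted p 6.9e-05), Cd3e 5.78-fold lower (-2.53, adjusted p 3.7e-06) and Mki67 4.20-fold lower at 9.09 ± 0.17 (-2.07, adjusted p 2.8e-04). All 18 thymocyte genes (median -2.66, with bounds -2.56), all 17 mitosis genes (-1.72) and all 16 replication genes (-1.08) fell, with Ube2c at -1.64 and Mcm5 at -1.53. The camera adjusted p values were 3.9e-14, 4.6e-10 and 2.8e-08, and the adjusted p with an estimated correlation was 0.372 for each. Of 6 neutrophil genes 5 fell (median -2.74, with bounds -1.55; camera adjusted p 0.00159, and adjusted p 0.372 with an estimated correlation), among them S100a9 at -4.39 and S100a8 at -3.93, and the median was -1.42 without the filter. Of 3 erythroid genes 2 fell, with Alas2 at -4.79 (median -2.25, -0.83 with the mean of all probe sets; camera adjusted p 0.0203, and adjusted p 0.372 with an estimated correlation), and the call was lost without the filter (adjusted p 0.070). Other large falls were Ccl20, a chemokine gene, at -4.47, Saa1, an acute-phase gene, at -4.02, Rasal3 by at least 14.0-fold (-2.18 with the mean of all probe sets) and Ttr by at least 7.33-fold (12.1-fold without untreated replicate 3). Among the other large rises, Cox8b was at least 6.92-fold higher and C1qtnf9 differed by 3.41. Cdkn1a stayed higher (10.35 ± 0.20, difference 1.48, adjusted p 3.3e-04), whereas Mdm2 read 6.95 ± 0.17 (-0.33, adjusted p 0.056) and was called lower without untreated replicate 2 (-0.39, adjusted p 0.042), day 4 replicate 2 (-0.33, 0.047) or day 7 replicate 3 (-0.42, 0.035). Mdm2 was also called lower with array weights (-0.42, adjusted p 0.0082), after centring on the kept genes (-0.36, 0.035) and at a level of 6 (-0.33, 0.048). Of 20 p53 targets 12 rose and 4 fell, 5 adjusted over the list alone (median 0.64, adjusted p 0.0911), a list called without the filter on dim genes (0.60, adjusted p 0.030).

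In all, 5915 genes differed at day 7, 3509 higher (59.3%) and 2406 lower, of which 941 and 992 by at least 2-fold. The groups did not overlap for 6826 genes (62.4%, against 10% by chance). Nor did they for 132 of the 133 named genes past the threshold, which the naming rule favours, the exception being Pecam1. The median of all genes stood at 0.0885. Centring on the epithelial list moved it by 0.075 and gave 2801 higher and 1446 lower (66.0%), and centring on the 4 stromal lists moved it by -1.19 and gave 205 and 9161 (2.19%). The 3-prime minus 5-prime values were 2.51 ± 0.21 for Actb and 0.90 ± 0.21 for Gapdh, a difference from untreated of 0.234 (exact permutation p 0.2) and -0.00341 (p 1).

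The comparison of day 7 with day 4 asked what changed between the 2 times. Thymocyte and division genes were higher at day 7 than at day 4. A difference in the cells left by the depletion cannot be told apart from a change in the thymus. Ptprc rose by 4.87 (adjusted p 5.2e-06, and 2.51 with the mean of all probe sets), Cd3e by 1.42 (adjusted p 1.1e-04) and Mki67 17.6-fold (4.13, SE 0.26, adjusted p 1.5e-05, n = 3 per group). The rise of Cd3e starts from its tied day 4 value and may be a lower bound. Rag1 rose by at least 75.4-fold, Cd8b1 by at least 20.5-fold, Ccr9 by at least 17.8-fold, Trbv1 by 5.46 and Dntt, an enzyme gene of receptor diversity, by 4.62, and the mean of all probe sets gave 1.88 for Ccr9 and 2.74 for Trbv1. Of 18 thymocyte genes 15 rose (median 3.09, with bounds 2.90). Of 17 mitosis genes 16 rose, 17 adjusted over the list alone (median 3.45, with bounds 2.60; 2.03 with the mean of all probe sets), with Ube2c at 4.31, and of 16 replication genes 15 rose (median 1.16, with bounds 1.0), with Mcm2 at 1.94. The camera adjusted p values were 1.6e-23, 2.8e-24 and 2.0e-14, and with an estimated correlation the adjusted p values were 0.147, 0.196 and 0.270. All 3 erythroid genes rose (median 2.14, with bounds 1.13; camera adjusted p 0.00412, and adjusted p 0.270 with an estimated correlation), with Alas2 at least 1.51-fold higher, a call lost without the filter (adjusted p 0.078). Of 12 DNA repair genes 5 rose, 7 adjusted over the list alone, and 1 fell, with Lig1 at 1.10 (median 0.34, camera adjusted p 0.00427, and adjusted p 0.270 with an estimated correlation; 0.71 after centring on the epithelial list and -0.19 on the 4 stromal lists).

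Vascular genes were higher at day 7 than at day 4. Of 17 endothelial genes 12 rose, 16 adjusted over the list alone (median 1.84, with bounds 1.78), with Erg, an endothelial transcription factor gene, 4.19-fold higher (1.03 on the log2 scale with the mean of all probe sets) and Robo4 at least 2.64-fold. Pecam1 rose by at least 2.84-fold from 2.92 ± 0.21, below the detection level (adjusted p 0.0068). Of 11 pericyte and smooth muscle genes 7 rose and 1 fell (median 0.87, with bounds 0.82), with Tagln, a smooth muscle gene, at 3.06. Of 6 mesothelial genes 2 rose, 4 adjusted over the list alone (median 0.73; 1.10 after centring on the epithelial list). The camera adjusted p values were 3.7e-09, 0.00194 and 0.00837, and with an estimated correlation the adjusted p values were 0.354, 0.270 and 0.419. Of 5 endothelial adhesion genes 2 rose (median 0.28, camera adjusted p 0.0206, and adjusted p 0.270 with an estimated correlation), with Icam2 at 2.66, and of 12 angiogenesis genes 5 rose and 1 fell (median 0.48, camera adjusted p 0.00845, and adjusted p 0.270 with an estimated correlation), with Esm1 at 2.55. These 2 medians were 0.65 and 0.85 after centring on the epithelial list and turned to -0.25 and -0.06 after centring on the 4 stromal lists, and the angiogenesis median was 0.79 without the filter. Dll4 rose by 0.73 (adjusted p 0.0048) and Kitl by 0.66 (adjusted p 0.011), values of 1.10 and 1.04 after centring on the epithelial list, and the Kitl call was lost with the mean of all probe sets (0.75, adjusted p 0.052). Ccl25 rose by 0.37 (adjusted p 0.017). The Ccl25 call was lost without day 4 replicate 2 (0.36, adjusted p 0.057) or 3 (0.35, 0.051), without day 7 replicate 2 (0.37, 0.058) or 3 (0.38, 0.050), and with the mean of all probe sets (0.18, 0.063). Centring on the epithelial list gave 0.75 for Ccl25, and centring on the 4 stromal lists turned it.

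Stress and lipid genes that were low at day 4 were higher at day 7. All 14 immediate early genes rose (median 1.73, camera adjusted p 1.1e-10, and adjusted p 0.270 with an estimated correlation), with Fosb at 3.42, Nr4a1 at 3.44 and Zfp36 at 2.24. Of 10 cholesterol synthesis genes 7 rose, and adjusted over the list alone 7 rose and 1 fell (median 1.18, camera adjusted p 4.6e-06, and adjusted p 0.270 with an estimated correlation; 0.63 with the mean of all probe sets), with Idi1, an isoprenoid enzyme gene, 6.38-fold higher (adjusted p 1.0e-05) and Hmgcs1 at 1.35. Of 10 hypoxia and glycolysis genes 2 rose (median 0.26, camera adjusted p 0.0163, and adjusted p 0.270 with an estimated correlation), a median of 0.63 after centring on the epithelial list that turned to -0.27 on the 4 stromal lists. Its member Ldha, at 0.45, was 0.83 after centring on the epithelial list and turned after centring on the 4 stromal lists.

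Antigen, interferon and complement genes were lower at day 7 than at day 4. Of 10 tissue-restricted antigens 6 fell, 8 adjusted over the list alone (median -1.59, camera adjusted p 0.00412, and adjusted p 0.533 with an estimated correlation), with Apoa4 at -2.45 and Reg3g at -1.80. Of 15 interferon response genes 9 fell, 11 adjusted over the list alone, and 1 rose, the chemokine gene Cxcl10 at 1.13, while the regulator Irf7 differed by -1.51 (median -0.48, camera adjusted p 0.00908, and adjusted p 0.497 with an estimated correlation; -0.11 after centring on the epithelial list). Of 7 complement genes 5 fell, 6 adjusted over the list alone, with Cfb at -1.69 (median -0.72, camera adjusted p 0.0116, and adjusted p 0.497 with an estimated correlation; -0.35 after centring on the epithelial list). Of 10 MHC class II genes 3 fell, with the protease gene Ctss at -1.14 (median -0.36, camera adjusted p 0.0416, and adjusted p 0.731 with an estimated correlation). The MHC class II call was lost without day 4 replicate 2 (-0.28, adjusted p 0.080), day 7 replicate 1 (-0.37, 0.053) or day 7 replicate 3 (-0.32, 0.107), and the median turned to 0.016 after centring on the epithelial list. Il7 fell by 0.55 (adjusted p 0.0030), a call lost after centring on the epithelial list (-0.18, adjusted p 0.496). Fgf7 differed by -0.84 (adjusted p 0.11) and was called lower without untreated replicate 1 (adjusted p 0.033) or 2 (0.024), and Pdgfra differed by -0.61 (adjusted p 0.066) and was likewise called without untreated replicate 1 (0.048) or 2 (0.023). Cdkn1a differed by -0.45 (adjusted p 0.11) and was called lower without untreated replicate 2 (0.031). Bmp4 differed by -0.05 (adjusted p 0.89), Foxn1 by -0.18 (0.33), Fgf21 by -0.14 (0.81), Cxcl12 by 0.05 (0.82), Epcam by -0.29 (0.29) and Mdm2 by -0.02 (0.93). Besides Ttr, at least 5.56-fold lower, the largest falls were the acute-phase genes Saa3 at -3.62 and Saa1 at -3.44, Lypd8 at -3.56, Reg3b, encoding an antimicrobial lectin, at -3.29 and the kallikrein gene Klk1b16 at -3.11.

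Between day 4 and day 7, 2991 genes differed, 1070 higher (35.8%) and 1921 lower, of which 418 and 366 by at least 2-fold. The groups did not overlap for 5655 genes (51.7%, against 10% by chance). Nor did they for any of the 116 named genes past the threshold, which the naming rule favours. The median of all genes stood at -0.101, and the split moved with the scaling, to 1349 higher and 1492 lower after centring on the mean of the kept genes (47.5%), 1201 and 1408 after quantile normalization (46.0%), 1595 and 354 after centring on the epithelial list (81.8%) and 400 and 7160 on the 4 stromal lists (5.29%). Centring on the epithelial list moved the median of all genes by 0.373 and on the 4 stromal lists by -0.532. The 3-prime minus 5-prime values were lower at day 7 than at day 4, by -0.618 for Actb and -0.474 for Gapdh (exact permutation p 0.1 each).

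**Figure D3:**
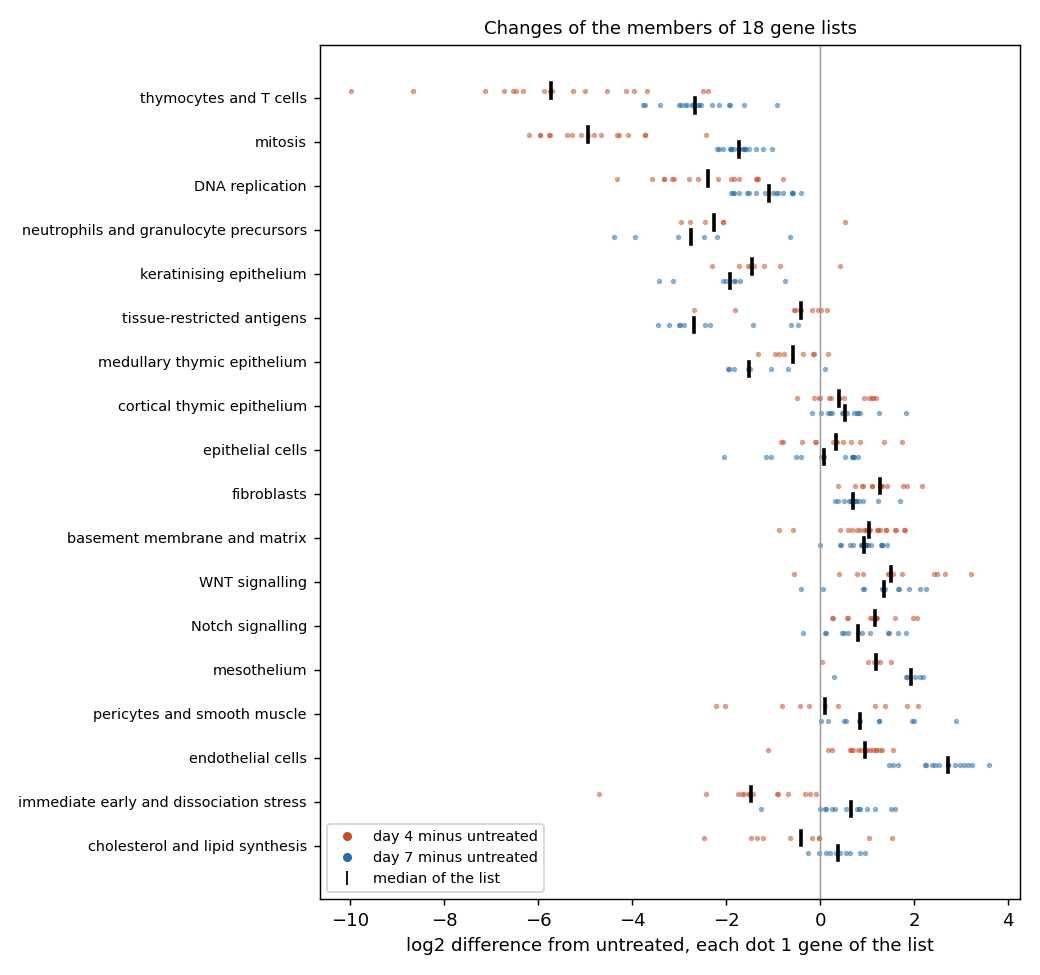
Log2 differences from untreated of the tested members of 18 gene lists at day 4 (orange dots) and day 7 (blue dots), with the list medians (black ticks). The endothelial median was 0.95 at day 4 and 2.71 at day 7, the thymocyte median -5.73 and -2.66, and the cortical (0.52), fibroblast (0.69) and pericyte (0.85) medians at day 7 turned below 0 after centring on the 4 stromal lists. That centring moved every gene by -1.19 at day 7, so any smaller rise turns.

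Across the 3 groups, 7584 of 10937 genes differed by the F-test. Relative to untreated, 3044 genes were higher at both times, 1775 lower at both times and 42 opposite. Independent lists of the same sizes would share 1468 and 515 genes. In 20 simulations of unchanged groups, at most 0 genes changed in the same direction at both times. With unchanged groups few genes would pass the threshold at either time. The 0 therefore does not show how much of the excess comes from the shared untreated arrays, and part of it may. Of the 2342 genes that fell at day 4, 734 were higher at day 7 than at day 4, and 480 of these were still below untreated. Of the 4574 that rose at day 4, 1424 were lower at day 7 than at day 4, and 711 of these were still above untreated. At day 7, 312 genes were higher and 403 lower than in both other groups.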

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

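The tests on the shares of fibroblast, epithelial, medullary and thymocyte RNA were chosen after the results were seen, and the counts over other splits of the arrays before. The fat tests were written before their counts were seen but after the rises of Adipoq and Cox8b were, and the white fat test was judged void after its count was seen, under the last of 3 detection conditions tried. The difference between the day 7 and day 4 effects, tested as day 7 against day 4, put 2991 genes in this part. Among the lists it was 3.09 for thymocytes, 3.45 for mitosis, 1.16 for DNA replication, 0.338 for DNA repair, 2.14 for erythroid cells, 1.84 for endothelium, 0.278 for endothelial adhesion, 0.865 for pericytes, 0.727 for mesothelium, 0.477 for angiogenesis, 0.257 for hypoxia, 1.73 for immediate early genes and 1.18 for cholesterol synthesis (median log2). It was -1.59 for tissue-restricted antigens, -0.479 for the interferon response, -0.357 for MHC class II and -0.721 for complement. Among the fixed genes it was 0.727 for Dll4, -0.552 for Il7, 0.663 for Kitl, 0.375 for Ccl25, 4.87 for Ptprc, 1.42 for Cd3e, 4.13 for Mki67 and 2.58 for Pecam1, of which only a bound of at least 1.51 can be read, since Pecam1 lay below the detection level at day 4. The Cd3e value may also be a bound, since its day 4 value was tied on all arrays.

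Other splits of the 6 arrays of a comparison are too few for a share under 0.05, since there are 10. In each of the 3 comparisons 1 of 10 splits, the real one, gave as many genes, with 6916, 5915 and 2991 genes and 0 in the highest other split. For the lists the real values were 14, 22 and 17, and the highest other splits gave 23, 21 and 15. At day 4, 4 of the 10 splits shifted as many lists as the real one, against 1 of 10 in each of the other comparisons. Of 100 drawn splits of the 9 arrays, 1, the real one, gave as many genes across the groups (7584, highest other 1040), and 1 as many genes changed the same way at both times (4819, highest other 532), so chance in how these 9 arrays fall into groups can be excluded for these counts, while differences between pools of mice are not covered if the samples of a group share a pool.

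Fibroblast genes rose at day 4 while thymocyte RNA was nearly gone, and a smaller share of thymocyte RNA would raise all stromal genes alike. The fibroblast list instead rose against the keratinising list by 2.51 (SE 0.50), so these 2 lists did not move alike. They were compared after their opposite directions were seen, and a separate fall of keratinising genes would give the same value. The difference therefore does not exclude that loss of thymocyte RNA raised the fibroblast list. Relative to the fibroblast list mean, Bmp4 moved by 0.181 (SE 0.19) at day 4, as a larger share of fibroblast RNA would give. At day 7 against untreated Bmp4 moved by 0.610 (SE 0.223), when the endothelial list mean also rose, by 2.56 (SE 0.53). Fgf7 moved by 1.67 (SE 0.33) at day 4, or 0.657 (SE 0.114) with the mean of all probe sets. Each SE covers the arrays and not the spread of genes within a list. Loxl1, a member of the fibroblast list, also rose above the list mean at day 4. Against the endothelial list mean Bmp4 moved by 0.63 (SE 0.57) at day 4 and by -1.18 (SE 0.55) at day 7, both against untreated. These values therefore do not exclude a larger fibroblast share for either gene, nor an endothelial share for Bmp4 at day 4 or day 7. Il7 rose relative to the epithelial list mean by 1.14 (SE 0.15). Krt5, a member of that list, also rose above the list mean, so a larger epithelial share is not excluded for Il7. A larger fibroblast share was not tested for Il7. A change within cells after irradiation was not tested for these genes, and the higher 3-prime minus 5-prime values at day 4 stay open as a technical source.

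Tissue-restricted antigens were lower at day 7. The epithelial list exceeded them by 2.21 more than in untreated (SE 0.25, which does not cover the spread of genes). The epithelial mean itself moved by -0.075 (SE 0.197), with genes moving both ways. Epcam differed by -0.40 (adjusted p 0.115), or -0.65 without untreated replicate 3 (adjusted p 0.0029). These values argue against a lower share of all epithelial RNA as the only source, but do not exclude that it contributed. The medullary list itself was lower (-1.30, SE 0.37), but the antigens fell further than that list by 0.988 (SE 0.104). A smaller share of medullary cells and lower expression within them cannot be told apart in pooled cells, since the antigens are made by subsets of medullary cells, and both may contribute.

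Some genes that fat expresses were higher at day 4, most of all in replicate 1, where Adipoq read 9.39 against 6.34 and 7.10 in the other day 4 arrays. Of 6 white fat genes with a probe set, 1 lay above all untreated arrays on every day 4 array, which met the bound set beforehand against white fat, but Adipoq alone reached the detection level on every day 4 array, and values below that level have no order, so this count excludes nothing. Of 7 brown fat genes 3 lay above all untreated arrays on every day 4 array, Cox8b, Cidea (adjusted p 0.042) and Ucp1 (0.087), while Cox7a1 (0.096) and Fabp3 (-0.16, 0.642) did not pass and Elovl3 and Otop1 lay near the floor. White or brown fat around the thymus cannot be told apart from a change within the thymus, since on day 4 replicate 2 Ucp1 and Cidea read 3.18 and 3.45, below the detection level and close to the highest untreated values of 2.86 and 3.38. On the day 4 arrays Cox8b read 8.49, 7.86 and 8.04, Cyp2e1 8.42, 6.80 and 6.33, and Car3 12.55, 9.84 and 10.62.

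The 3-prime minus 5-prime value of the control probe sets, outside the gene comparisons, was higher at day 4 than in untreated by 0.852 for Actb and by 0.470 for Gapdh. Among 2479 probe sets without a single gene symbol that were bright enough to test, 1662 passed the threshold at day 4 (565 higher, 1097 lower) and 1511 at day 7 (399 higher, 1112 lower).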

How the results depend on the processing

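Centring on the epithelial list and on the 4 stromal lists was chosen after seeing the data, and all other alternatives before. Of 385 called named gene results, 317 kept their call in every alternative run on them, 68 lost it in at least 1, and 0 turned. The level of 6, the mean of all probe sets and quantile normalization covered 341, 373 and 383. The naming rule favours genes with a small adjusted p or a large change, so these counts do not describe all called genes. These counts leave out centring on the 4 stromal lists, for which, as decided after seeing it, only turned signs were counted: it moves all genes alike, by -0.658, -1.19 and -0.532 in the 3 comparisons, so a turn only marks an effect smaller than that. It turned 52 of 385 genes and 15 of 53 called lists (0 of 14 at day 4, 11 of 22 at day 7, 4 of 17 between the times). The mean of all probe sets moved 56 of the gene results by over 1.5 times on the log2 scale, and leaving out 1 array moved 3. Lower bounds of fold changes were not part of these counts. Leaving out 1 array moved the bounds of Cyp2e1, Alas2, Mpo and Ttr by over 1.5 times. Testing every probe set on its own gave 12579, 10857 and 4661 changes in the 3 comparisons in the order above, 13629 across the groups and 8912 at both times, because more features were tested. A difference of at least 2-fold gave 2540, 1933, 784 and 1404 at both times, and an adjusted p of 0.01 gave 1272 between the times, by construction. Leaving out 1 array gave 6093 to 6976 genes at day 4, 4753 to 6159 at day 7, 1760 to 3464 between the times (1760 without day 7 replicate 2, 1905 without day 4 replicate 2), 6532 to 7669 across the groups, 3878 to 5118 at both times, and 13 to 18, 22 to 26 and 16 to 19 lists. Centring on the epithelial list gave 1949 between the times and 3022 at both; the cause was not tested. On the 4 stromal lists the shift of all genes made 9161 of 9366 calls at day 7 and 7160 of 7560 between the times lower. Camera with an estimated correlation gave 0, 0 and 0 lists, as the estimate exceeded the preset in 36 of 38 lists (median 0.298), while fry, which does not compare a list with other genes, gave 29, 29 and 20. In the other 14 camera settings 12, 18 and 15 of the called lists kept their call. The inflammatory list at day 7 (median 0.104) turned to -0.00704 without untreated replicate 3 (adjusted p 0.041), within -0.0720 to 0.241 on leaving out 1 array; the cause was not tested. MHC class II between the times turned to 0.0160 (adjusted p 0.048) after centring on the epithelial list, which moves all genes by 0.373 there. Same-numbered samples did not deviate together (residual correlations of -0.118 to 0.184, 3 of 9 over 0.1), so the replicate block, with 6669, 5588 and 2614 genes, 7124 across the groups, 4555 at both times and 17, 21 and 19 lists, pairs nothing; under it the regeneration factors at day 7 had an adjusted p of 0.063. Signal near the floor limits dim genes: without the filter 38 of the 385 calls were lost.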

Other observations

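The tests of 1 list mean against another were chosen after the results were seen. The parathyroid hormone gene Pth read 11.26 in untreated and 13.30 at day 7 (difference 2.04, adjusted p 2.5e-04) and had risen by 1.14 at day 4 (adjusted p 0.0035), and the neuroendocrine gene Chga rose by 2.44 at day 7; the parathyroid list had 2 tested members and was not tested as a list. Mesothelial genes were already higher at day 4, when 5 of 6 rose (median 1.18, adjusted p 0.188), with Wt1 at 1.51. Of the other lists that were not tested, B cells, dendritic cells, Schwann cells and adipocytes had 2, 2, 1 and 1 members above the detection level, and innate lymphoid cells and lymphatic endothelium 0. In these, both B-cell genes passed neither side at day 4 over all genes and fell adjusted over the list alone, Cd79b was at least 2.31-fold lower at day 7, Ccr7 at least 1.98-fold lower at both times, Mbp, a myelin gene, fell by 0.85 at day 4, and Adipoq rose by 3.32 at day 4 (adjusted p 0.0037).

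The lists below were not shifted, with adjusted p values from camera. At day 4, of 15 inflammatory genes 4 rose and 6 fell (median -0.41, 0.225), with Il33 at 1.55, of 19 BMP genes 12 rose and 3 fell (0.80, 0.188), with Bmper at 2.20, of 13 TGF-beta genes 7 rose (0.46, 0.186), of 11 FGF genes 7 rose and 1 fell (0.98, 0.188), and of 10 regeneration factors 8 rose and 2 fell (0.90, 0.101). Of 9 homing factors 8 rose (0.55, 0.0639), and the list was called without untreated replicate 3 (0.72, adjusted p 0.025), without the filter (0.55, 0.013) and after centring on the epithelial list (0.25, 0.040). Of 12 angiogenesis genes 7 rose and 1 fell (0.54, 0.547), with Vegfd at 3.28, and of 10 hypoxia genes 2 rose and 5 fell (-0.37, 0.0734), a list called without untreated replicate 1 (adjusted p 0.045). Of 11 senescence genes 5 rose and 2 fell (0.35, 0.560), with Mmp3 at 2.76, of 15 interferon genes 7 rose and 2 fell (0.33, 0.547), of 10 MHC class II genes 2 rose and 1 fell (0.17, 0.727), of 10 MHC class I genes 4 rose (0.17, 0.547). Signs differed in 4 lists at day 4: tuft-like cells (2 rose, 1 fell of 5; median 0.17, mean 0.02, camera down, 0.689), endothelial adhesion (2 rose, 1 fell of 5; 0.03, mean -0.29, camera down, 0.755), pericytes (4 rose, 3 fell of 11; 0.10, mean 0.11, camera down, 0.876) and oxidative stress (5 rose, 4 fell of 12; 0.07, mean 0.22, camera down, 0.755).

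At day 7, of 15 interferon genes 5 fell (median -0.08, adjusted p 0.0992), with Oas1a at -0.82, and the list was called without untreated replicate 3 (-0.15, 0.030) and without day 7 replicate 2 (-0.14, 0.046). Of 10 MHC class II genes 2 rose and 2 fell (-0.12, 0.312), a list called without untreated replicate 3 (-0.26, 0.046), and of 10 MHC class I genes 3 rose and 2 fell (-0.06, mean 0.01, 0.825). Of 5 tuft-like genes 1 fell, Il17rb by at least 3.34-fold (-0.87, 0.0892), and the list was called without untreated replicate 3 (-1.27, 0.032) and after centring on the epithelial list (-0.79, 0.034). Of 15 inflammatory genes 2 rose and 6 fell, with Cxcl9 at -2.03 (0.10, mean -0.46, camera down, 0.169; 0.18 and 0.040 after centring on the epithelial list). Of 6 macrophage genes 1 rose and 3 fell (-0.82, 0.194), with Lyz2 at -2.08. Of 12 DNA repair genes 2 rose and 6 fell (-0.51, 0.0911), a list called without the filter on dim genes (-0.80, adjusted p 0.023), and of 11 senescence genes 4 rose and 1 fell (0.66, 0.353), of 13 TGF-beta genes 7 rose and 1 fell (0.74, 0.0992; 0.57 and 0.037 without the filter) and of 10 hypoxia genes 2 rose and 3 fell (-0.07, 0.350). Of 12 oxidative stress genes 5 rose and 2 fell (0.34, 0.406), of 14 immediate early genes 4 rose and 1 fell (0.66, 0.260), of 10 cholesterol genes 4 rose (0.37, 0.178) and of 5 endothelial adhesion genes 3 rose (0.28, 0.206).

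Between the times, of 14 fibroblast genes 5 fell and 1 rose (median -0.50, adjusted p 0.0616), a list called without any 1 of untreated replicates 1 (0.045) and 2 (0.046), day 4 replicates 1 (-0.53, 0.048) and 2 (-0.60, 0.010) and day 7 replicates 1 (-0.55, 0.039) and 2 (-0.55, 0.026). Of 8 medullary genes 4 fell (-0.87, 0.128) and of 8 keratinising genes 3 fell (-0.72, 0.0637), and both were called without untreated replicate 3 (adjusted p 0.024 and 0.0025), the latter also without day 7 replicate 2 (-0.77, 0.048). Between the times, centring on the epithelial list gave calls for fibroblasts (-0.13, 0.0079), medulla (-0.50, 9.7e-04), keratinising epithelium (-0.35, 9.6e-05), tuft-like cells (-0.59, 0.0060) and neutrophils (-0.41, 0.0029). The mean of all probe sets gave them for fibroblasts (-0.54, 0.033), keratinising epithelium (-0.84, 0.040) and cortex (0.20, 0.044), centring on the kept genes for fibroblasts (-0.43, 0.040) and keratinising epithelium (-0.65, 0.027), and leaving out the filter for fibroblasts (-0.50, 0.022) and cortex (0.20, 0.035). Of 13 Notch genes 2 rose and 7 fell (-0.61, 0.179), of 20 p53 targets 3 rose and 7 fell (-0.31, 0.285), of 10 MHC class I genes 1 rose and 5 fell (-0.26, 0.362), of 14 cortical genes 3 rose and 2 fell (0.20, 0.0637), of 13 epithelial genes 1 rose and 2 fell (-0.29, 0.325) and of 5 tuft-like genes 1 fell (-0.97, 0.107). Of 6 macrophage genes 2 fell (-0.42, 0.838), of 6 neutrophil genes 2 fell (-0.79, 0.285), of 15 inflammatory genes 3 rose and 5 fell (-0.38, 0.860), with Ccl8 at -2.75 and Ccl5 at -2.43, of 12 WNT genes 2 fell (-0.25, 0.776), of 13 TGF-beta genes 1 rose and 2 fell (-0.18, 0.551), of 10 regeneration factors 1 rose and 1 fell (-0.16, 0.879) and of 12 oxidative stress genes 1 rose and 1 fell (0.10, 0.306). Signs differed between the times for senescence (2 rose, 3 fell of 11; median -0.21, mean 0.22, 0.879), BMP (4 rose, 2 fell of 19; -0.05, mean 0.06, 0.325), FGF (3 rose, 1 fell of 11; -0.03, mean 0.14, 0.306), matrix (3 rose, 2 fell of 21; -0.17, camera up, 0.989) and homing (3 rose, 2 fell of 9; -0.10, camera up, 0.705). Adjusted over the list alone, the counts between the times were 8 fallen and 1 risen for fibroblasts, 5 fallen for medulla, 4 for keratinising epithelium, 3 for neutrophils and 3 for tuft-like cells, 2 risen and 2 fallen for macrophages, 4 and 2 for cortex, 1 and 4 for epithelium, 3 and 8 for Notch, 1 and 6 for MHC class I, 5 and 7 for inflammatory genes, 1 and 5 for WNT, 2 and 4 for senescence, 4 and 3 for BMP and 4 and 2 for FGF.

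The mitosis list mean rose against the thymocyte list mean by 0.881 (SE 0.108) at day 7 against untreated, and no such value is given for day 4, where both means lay below the detection level. The endothelial list mean rose against the fibroblast list mean by 1.79 (SE 0.57) at day 7 against untreated, and by 2.24 (SE 0.22) at day 7 against day 4. Against the endothelial list mean Bmp4 moved by 0.63 (SE 0.57) at day 4 and by -1.18 (SE 0.55) at day 7 against untreated, and by -1.81 (SE 0.14) between the times.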
